A study of Mus musculus with 6 samples.

How the data were processed

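Circular RNAs (circRNAs), transcripts closed into a ring by joining a downstream splice donor to an upstream acceptor, were profiled in the hippocampus of adult male C57BL/6J mice. The labels put 3 libraries in a chronic unpredictable stress (CUS) group and 3 in a Control group. The stress schedule lasted 4 weeks and combined randomly ordered mild stressors such as restraint, cold swimming and cage tilting, per the labels' protocols. The labels call the samples independent without saying whether each came from 1 mouse, so p-values measure the spread between these samples. Per the labels' protocols, RNA was selected for poly(A) in repeated rounds before stranded libraries with molecular identifiers were sequenced as read pairs. A ring has no poly(A) tail of its own, so this selection can lower and distort the recovery of circRNAs.

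The authors deposited 1 table of 10652 circRNAs with an identifier, Ensembl host gene identifiers, a class (exon, intron or intergenic) and 1 value per library. The deposited values are on a log10 scale, and a circRNA without a value in a library is listed at 0. The header names no unit. After taking 10 to each value, 100% of the values under 300 steps in each library lay within 0.05 of a whole multiple of one library-specific step, with a lowest value of 17 steps in each of the 6 libraries. The linear values are therefore levels divided by a factor for the library, and what 1 step stands for is not given in the sources used here. The mm9 build, StringTie, DESeq and edgeR appear in the submitters' processing notes without a role, and the circRNA caller is not given in the sources used here. The table was used without circRNA coordinates. Host symbols and gene positions were looked up by Ensembl identifier in GENCODE vM21 (GRCm38), where 4467 of 4483 host identifiers matched. Positions below are those of the host gene on GRCm38, not of the circRNA.

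Levels are 10 to the deposited value, and the inverse of the step is called the relative depth of each library. It reflects the library's scale factor, and whether that factor follows sequencing depth is not given in the sources used here. Relative depth was 100%, 95.8% and 90.8% of the deepest library in Control replicates 1 to 3 and 81.9%, 89.8% and 88.8% in CUS replicates 1 to 3. The number of reads behind a value is unknown, so no counting interval or floor is given, and a circRNA listed at 0 is not shown to be absent. Values that include a 0 are given per library and not as a mean with SD. No fold is given against a group listed at 0 in all of its libraries. Of 786 circRNAs with several host identifiers, 583 were assigned to their only protein-coding host and 203 were left out of host sums, as were the 658 intergenic circRNAs. Levels were then summed over the 9791 circRNAs of 3772 hosts.

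Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend) on log2(level + 45.5), where the pseudocount is the median over libraries of the lowest level above 0. Fold changes are on that scale and understate the change of low circRNAs. A single library at 0 can also enlarge them, as for the Cacna2d1 host sum, whose log2 difference of -1.62 rests on CUS replicate 2 at 0. A circRNA or host was tested when it was above 0 in at least 3 of the 6 libraries, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. A looser count used an unadjusted p under 0.05 with at least a 2-fold change. Gene lists with at least 5 tested members were tested on host sums with limma's camera at a preset correlation of 0.01, then with an estimated correlation. They were also tested with fry, which was run without a variance trend. Single values per library were compared with an exact two-sided permutation test of the difference of means, whose smallest possible p for 3 against 3 is 0.1. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

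Groups, tests, alternatives, 21 gene lists and the rule for named genes were fixed before the data were examined. The lists covered known brain circRNA hosts, hosts known from work on depression or stress, presynaptic genes, postsynaptic genes, GABA and monoamine genes, ion channels, adhesion and axon guidance, chromatin and cohesin, RNA binding and splicing, ubiquitin enzymes, kinases and phosphatases, small GTPases and cytoskeleton, and the glucocorticoid response. Cell and region lists covered oligodendrocytes, astrocytes, microglia, vascular and choroid cells, dentate granule cells, CA pyramidal cells, interneurons and neighbouring tissue. With fewer than 20 circRNAs past the threshold, the rule named the 10 higher and 10 lower circRNAs of smallest unadjusted p whose mean over all libraries was above the median of those tested. It also named 5 hosts in each direction by the same order, the 10 most abundant circRNAs (1 of which is not reported here), the 2 to 4 members of smallest p in each tested list, and the most abundant circRNA of each depression host. Alternatives were other scalings, no trend, other filters, other pseudocounts, a replicate block and leaving out each library.

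The fit was tested on simulated data. With log2 values of small spread it recovered 200 of 200 changed circRNAs with 11 false calls. For CUS against Control among 5326 circRNAs with simulated reads of unequal weight, an adjusted p under 0.05 was reached by 0% of circRNAs changed 2-fold, 8% changed 4-fold, 24% changed 8-fold and 46% changed 16-fold. Among 2563 hosts simulated for the same comparison, the shares were 0%, 20%, 50% and 58%. The simulated reads assume an average of 75 steps per read, which the sources do not state, and the simulated libraries held more circRNAs above 0 than the real ones (5123 against 4606 in Control replicate 1, 4543 against 3991 in CUS replicate 1). The simulation also added no spread between samples beyond the drawing of reads. Its median SD of log2 levels within groups was 1.29 against 1.43 observed over tested circRNAs. Over the 100 most abundant it was 0.44 against 0.63. These shares are therefore rough and lean high. A doubling of the presynaptic list, simulated in the same way without added spread, was called by camera, with 0 other lists called.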

Results

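CircRNA levels were measured in 6 hippocampal libraries, 3 from mice under chronic unpredictable stress (CUS) and 3 from controls, to find circRNAs that differ with stress. Control replicates 1 to 3 held 4606, 4526 and 4329 circRNAs above 0, and CUS replicates 1 to 3 held 3991, 4238 and 4273. After division by each library's factor, summed levels were close in all libraries, from 1990260 in CUS replicate 3 to 2050720 in Control replicate 2. Of the 10652 circRNAs, 9524 (89.4%) were exonic, 470 intronic and 658 intergenic. Of all circRNAs, 3930 were each above 0 in only 1 library, while 804 were above 0 in all 6 libraries and carried 37.2% of the summed level.

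The circRNAs of highest mean included products of synaptic, adhesion and zinc finger genes. The highest was mmu_circRNA006520 of Tshz2, a zinc finger transcription factor gene at chromosome 2, 169633013 to 170071816, with a level of 6658 ± 3803 in Control and 8519 ± 4174 in CUS (SD, n = 3 each). The intronic mmu_circRNA005215 of Zfp532 (chromosome 18, 65579912 to 65689443) was at 5339 ± 1499 and 5596 ± 2086 (SD, n = 3 each). mmu_circRNA010387 of Fat3, an atypical cadherin gene (chromosome 9, 15910189 to 16501285), was at 4619 ± 1022 in Control and 5889 ± 1708 in CUS (SD, n = 3 each). mmu_circRNA009483 of Grm5, the metabotropic glutamate receptor 5 gene (chromosome 7, 87584168 to 88134907), was at 6356 ± 2080 in Control and 3769 ± 1050 in CUS (SD, n = 3 each). Exonic circRNAs of Strbp, Fmn2 and Plcl2 had higher means in CUS, at 6086 against 3720, 5427 against 3092 and 5443 against 2791. mmu_circRNA011363 of Gm47283, which lists a second host identifier, was at 3339, 3764 and 10889 in Control and 6693, 3405 and 3189 in CUS. The circRNA of Gm44901 was at 4646 in Control against 3906 in CUS. None of these 9 passed limma's test, with a lowest adjusted p of 0.656 for Plcl2. By host sum, Strbp (10426), Zfp532 (10300) and Fmn2 (8951) led 3772 hosts, and Lrp1b had the most circRNAs, 30, ahead of Csmd1 with 26 and Nbea with 24.

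**Figure D1:**
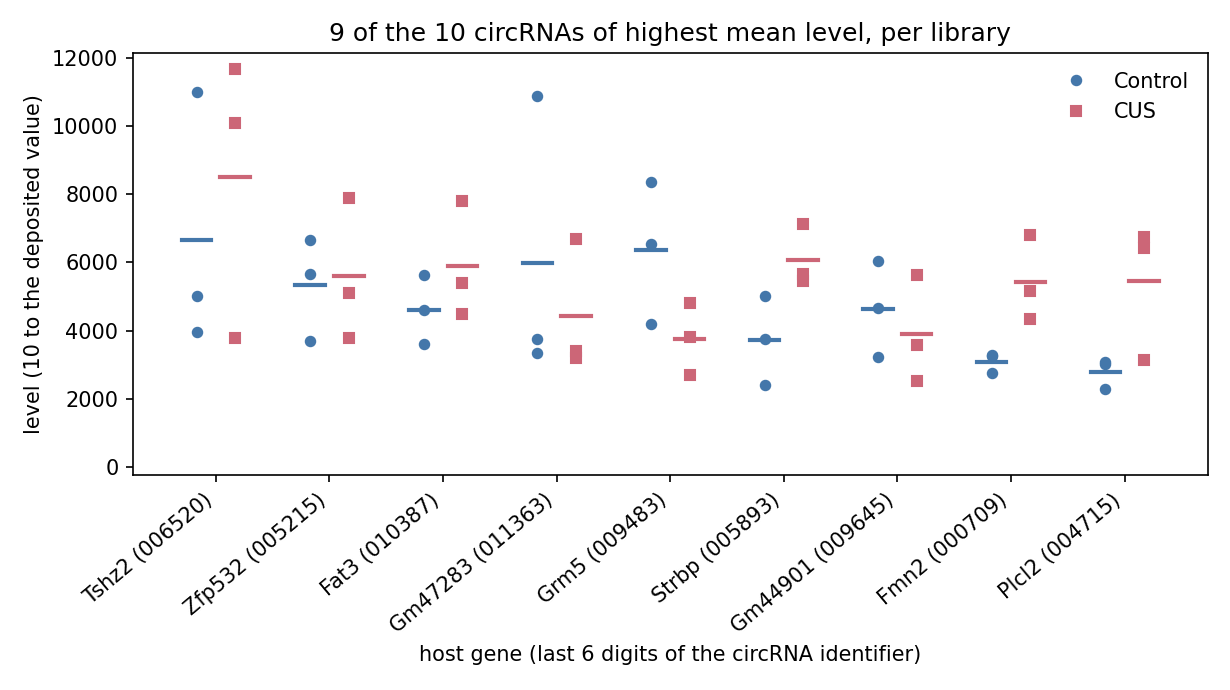
Level of 9 of the 10 circRNAs of highest mean in each library (y axis, 10 to the deposited value), with Control as circles, CUS as squares and group means as lines. The Tshz2 circRNA ranges from 3786 to 11673 among CUS libraries, and the Control and CUS libraries do not overlap for the Strbp, Fmn2 and Plcl2 circRNAs, where chance separates 3 from 3 libraries in 10% of circRNAs.

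Single circRNAs were compared between CUS and Control. mmu_circRNA008745 of Ubn2, a histone chaperone gene (chromosome 6, 38433950 to 38524825), was at 1064, 2531 and 2107 in CUS against 229, 802 and 258 in Control, a log2 difference of 2.15 with SE 0.74. mmu_circRNA009091 of Grin2b, which encodes the GluN2B subunit of the NMDA receptor (chromosome 6, 135713233 to 136173511), was at 1120, 694 and 535 in CUS and at 0, 0 and 71.8 in Control. mmu_circRNA004879 of Slc8a1, a sodium-calcium exchanger gene (chromosome 17, 81373105 to 81738377), was lower in CUS, at 244 ± 76.4 against 1407 ± 281 (SD, n = 3 each), with a log2 difference of -2.34 and SE 0.80. The summed level of the 11 Slc8a1 circRNAs overlapped between groups, at 4938, 5170 and 4093.5 in CUS and 4374, 3348.5 and 6522 in Control. mmu_circRNA009949 of Irf2, an interferon regulatory factor gene (chromosome 8, 46739732 to 46847458), was at 161 ± 30.9 in CUS and 1165 ± 231 in Control (SD, n = 3 each). None of these differences passed the adjusted threshold.

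Among the 10 higher circRNAs named by rule, 8 were listed at 0 in all 3 Control libraries. In CUS replicates 1 to 3 mmu_circRNA008369 of Mphosph9 was at 604, 1635 and 492, mmu_circRNA004646 of Zfp563 at 643, 586 and 677, and mmu_circRNA002411 of Sos2, a Ras exchange factor gene, at 625, 584 and 655. mmu_circRNA009656 of Prkcb, a protein kinase C gene, was at 327, 796 and 576. mmu_circRNA009133 of Tmtc1, mmu_circRNA004561 of Zfp943, mmu_circRNA004744 of Cntnap5c and mmu_circRNA002061 of Cep112 were the other four. Among the lower ones, mmu_circRNA001891 of Trim37 was at 1009, 282 and 668 in Control and listed at 0 in all 3 CUS libraries. The same held for mmu_circRNA001603 of Kif3a, a kinesin gene (473, 930 and 327 in Control), and for mmu_circRNA002294 and mmu_circRNA002292 of Dock4. The 2 Dock4 circRNAs differed by at most 12 steps in any library and may share reads. mmu_circRNA009951 of Irf2 was at 1361, 663 and 1189 in Control and 0, 183 and 130 in CUS. The other named Irf2 circRNA, mmu_circRNA009949, was at 1398, 935 and 1162 in Control and 142, 196 and 144 in CUS. With levels close in most libraries, the 2 Irf2 circRNAs may share reads. Paired circRNAs of Tmem132b, mmu_circRNA008388 and mmu_circRNA008391, were at 1741, 1422 and 1056 and at 1535, 1382 and 1088 in Control. In CUS they were at 672, 153 and 0 and at 684, 164 and 0. With levels this close in each library, the 2 Tmem132b circRNAs may share reads. mmu_circRNA006873 of Trim33 was at 181, 1729 and 1843 in Control and 0, 0 and 215 in CUS.

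Of 3896 circRNAs tested with limma, 0 passed at an adjusted p under 0.05, and the lowest adjusted p was 0.577. At an unadjusted p under 0.05 there were 234, 107 higher and 127 lower in CUS, where chance alone gives about 195, and 231 of them also reached a 2-fold change. Reads were simulated for this comparison at an assumed average of 75 steps per read and with no added spread between samples. There 8% of 4-fold changes among 5326 circRNAs passed, so most changes of that size would have been missed under those assumptions.

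CircRNA levels were then summed by host gene. Trim37, which encodes a ubiquitin ligase (chromosome 11, 87127077 to 87220683), was at 467 ± 249 in CUS against 2551 ± 839 in Control over 8 circRNAs (SD, n = 3 each), with a log2 difference of -2.43 and SE 0.65. Ncor1, a nuclear receptor corepressor gene (chromosome 11, 62316426 to 62458541), was at 883 ± 602 against 2470 ± 395 (SD, n = 3 each). Grin2b was at 4265 ± 985 in CUS against 1995 ± 1144 in Control (SD, n = 3 each), a log2 difference of 1.20 with SE 0.44. Map2k4, a kinase gene of the JNK pathway (chromosome 11, 65688243 to 65788297), was at 616, 2598 and 4090 in CUS against 307, 280 and 819 in Control, and 2 of its circRNAs had the same level (968) in CUS replicate 3. Rfx3, a ciliary transcription factor gene (chromosome 19, 27761721 to 28011166), was at 3488 ± 796 against 1469 ± 299 (SD, n = 3 each) over 18 circRNAs. Nphp4 was at 2839, 1641 and 1430 in CUS against 1082, 461 and 205 in Control, and Cyld, a deubiquitinase gene, at 1194, 2870 and 1133 against 753, 424 and 90.4. Alg9 was at 826, 524 and 1213 in Control and Gabra2, a GABA-A receptor subunit gene, at 1509, 593 and 503, and both were listed at 0 in all 3 CUS libraries. Mdga2 was at 1041, 1921 and 2564 in Control and 0, 1178 and 522 in CUS. Of 2227 hosts tested with limma, 0 passed, with a lowest adjusted p of 0.737. There were 127 at an unadjusted p under 0.05. Evenly spread p-values would give about 111, and the other splits of the 6 libraries into 3 and 3 gave 82 to 127.

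**Figure D2:**
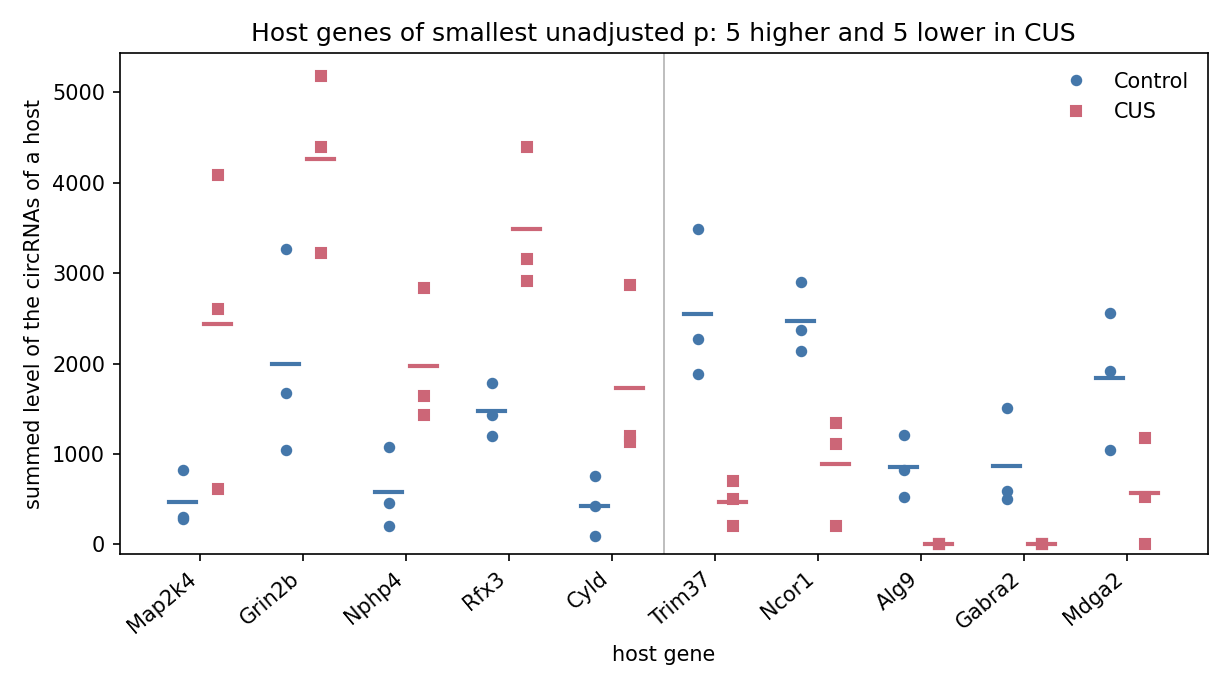
Summed circRNA level per host and library (y axis) for the 5 higher and 5 lower hosts of smallest unadjusted p, with Control as circles, CUS as squares and group means as lines. Trim37 lies between 1883 and 3493 in Control and between 204 and 699 in CUS, and Alg9 and Gabra2 are listed at 0 in CUS.

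Host genes were grouped by the lists fixed in advance. In the ubiquitin list 17 of 45 tested hosts had a higher and 28 a lower fitted value in CUS. Trim37 was the only host in any list with an adjusted p under 0.05 adjusted over the list alone (limma adjusted p = 0.025), while 0 of 45 passed over all hosts. That p was not corrected over the 18 lists, and it was above 0.05 without a trend (0.414), with 0.2 times the pseudocount (0.0557) and without any of Control replicates 1, 2 and 3 (0.476, 0.152 and 0.110) or CUS replicates 1 and 2 (0.0589 and 0.185). Trim33 was at 181, 1729 and 3011 in Control and 0, 538 and 487 in CUS.

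Among 38 postsynaptic hosts, 20 were higher and 18 lower, with Grin2b and Cnksr2 (3726 ± 935 against 1841 ± 571) on the higher side. Magi2, a synaptic scaffold gene (2197 ± 647 in CUS against 4702 ± 1220 in Control; SD, n = 3 each), and Grm5 (4258 against 7004) were on the lower side. Of 24 presynaptic hosts 10 were higher and 14 lower. Dnm1, a dynamin gene, was at 488, 93.3 and 564 in Control and listed at 0 in CUS. Unc13c, a synaptic vesicle priming gene, was at 536, 0 and 1037 in Control and 0, 0 and 73.4 in CUS, and Ppfia2 at 0, 164 and 0 against 1527, 428 and 0. Cadps was at 3783 ± 226 in CUS against 5230 ± 424 (SD, n = 3 each). Of 30 ion channel hosts 11 were higher and 19 lower, with Cacna1d at 198, 1326 and 1333 in Control and listed at 0 in CUS. Nalcn, a sodium leak channel gene, was at 1377 ± 472 in CUS against 3199 ± 908 in Control (SD, n = 3 each). The Nalcn sum holds mmu_circRNA003564 and mmu_circRNA003563, which differed by at most 16 steps in any library and may share reads. Host sums of Cadps, Adarb2 and Fmn2 also hold a pair with close levels. On the higher side, Cacna2d3 was at 1545, 471 and 813 in CUS against 0, 0 and 176, and Kcnma1, a potassium channel gene, at 752, 2646 and 764 against 246, 47.9 and 370. The 10 GABA and monoamine hosts split into 5 and 5, with Gabra2 listed at 0 in CUS and Gabrb2 at 0 in Control but at 737, 646 and 215 in CUS.

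In the RNA binding and splicing list 19 of 27 hosts were higher and 8 lower. Adarb1, an RNA-editing enzyme gene, was listed at 0 in Control and at 483, 532 and 315 in CUS, Dicer1 at 0 in Control and at 601, 549 and 247 in CUS, Srrm2 at 0 in CUS and at 495, 413 and 250 in Control, and Srpk2, a splicing kinase gene, at 1209 ± 422 in CUS against 2879 ± 1386 (SD, n = 3 each). Of 51 chromatin and cohesin hosts 20 were higher and 31 lower, with Brwd1 at 1335, 1205 and 1677 in CUS against 1135, 83.2 and 109 in Control and Ezh2, a histone methyltransferase gene, at 2067, 1232 and 764 against 579, 207 and 207. Of 58 kinase and phosphatase hosts 21 were higher, with Map2k4 of smallest p, and 37 lower, among them Pak3 at 1029, 196 and 0 in CUS against 1777, 1049 and 1157 in Control and Prkce at 3328 ± 1569 against 5738 ± 1128 (SD, n = 3 each). The small GTPase and cytoskeleton list had 24 higher and 37 lower of 61, with Arhgap35 at 613, 343 and 575 in Control and listed at 0 in CUS, and Rapgef6 at 637, 112.98 and 101 in CUS and listed at 0 in Control. Nf1 was at 528, 2453 and 660 in CUS against 2830, 2579 and 1742, with a log2 difference of -1.25 that was -1.90 without CUS replicate 2. Of 45 adhesion and axon guidance hosts 26 were higher and 19 lower, with Tenm3, a teneurin gene, at 2313 ± 318 in CUS against 4935 ± 1734 (SD, n = 3 each), Ptprk at 239, 179 and 176 in Control and listed at 0 in CUS, and Tenm4 at 1890, 2335 and 3300 in CUS against 683, 1014 and 2439. The glucocorticoid list had 7 higher and 4 lower of 11, with Ncor1 lower. Hspa4 was at 150, 473 and 416 in CUS against 263, 0 and 0. The list's summed level over 16 hosts with a circRNA was 5612 ± 1429 in CUS and 7026 ± 711 in Control (SD, n = 3 each). Ncor1 alone was at 883 in CUS against 2470 in Control, so the lower sum rests on that host. Of 38 known brain circRNA hosts 16 were higher and 22 lower, with Brwd1 and Satb1 (3611, 1754 and 707 in CUS against 1096, 335 and 492) on the higher side. On the lower side, Map4k4 was at 0, 834 and 606 in CUS against 1098, 547 and 2277, and Cacna2d1 at 3702, 0 and 2199 against 2272, 3187 and 1439, where the difference changed sign without CUS replicate 2 (log2 0.38).

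Cell and region markers were measured in the same way. Of 8 tested astrocyte hosts 5 were higher and 3 lower, with Gpc5 at 274 ± 86.3 in CUS against 745 ± 343 in Control (SD, n = 3 each), Gli3 at 0, 118 and 247 against 60.4, 0 and 0, and Slc4a4 at 1274, 1829 and 228 against 727, 277 and 285. Of 9 oligodendrocyte hosts 5 were higher and 4 lower, with Slc44a1 at 1427, 557 and 598 in CUS against 444, 0 and 556, Prr5l at 0, 0 and 598 against 616, 305 and 213, and Edil3 at 1271 ± 437 against 840 ± 470 (SD, n = 3 each). Of 11 dentate granule cell hosts 7 were higher, with Rfx3 of smallest p, and 4 lower, with Cntnap5a at 1798, 169 and 446 in CUS against 973, 2582 and 947. Of 6 CA pyramidal hosts 4 were higher and 2 lower, with Tenm3 lower and Cpne4 listed at 0 in Control and at 144, 272 and 381 in CUS. Of 7 interneuron hosts 5 were higher and 2 lower, with Adarb2 at 3270, 3147 and 1210 in CUS against 681, 1828 and 644 and Galntl6 at 0, 2453 and 236 in CUS against 973, 1704 and 1234. Summed over all hosts with a circRNA, CA pyramidal levels were lower in CUS despite more higher hosts, at 5483 ± 2157 against 8193 ± 1941 in Control. Most of that difference came from Tenm3, at 2313 in CUS against 4935 in Control. The groups overlapped, with CUS replicate 2 (7902) above Control replicates 1 and 2 (6576 and 7657). The sums were 5230 ± 1015 against 3571 ± 1472 for astrocytes, 7424 ± 2156 against 6124 ± 1627 for oligodendrocytes, 11395 ± 2314 against 9776 ± 2779 for dentate granule cells and 8669 ± 2659 against 6100 ± 2602 for interneurons (SD, n = 3 each). These sums were not tested. Microglial, vascular and choroid, and neighbouring tissue lists had fewer than 5 tested hosts and were not tested as lists.

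Camera called 0 of 18 lists, with a lowest adjusted p of 0.680, and 1 list, RNA binding and splicing, had an unadjusted p under 0.05 (limma camera p = 0.0447, and p = 0.225 with an estimated correlation). Fry's directional test called 0 lists, with 2 at an unadjusted p under 0.05. Fry's mixed test, which asks whether hosts change in either direction and does not compare a list with other hosts, had limma adjusted p-values under 0.05 for 5 lists. These were GABA and monoamine (0.00026), RNA binding and splicing (0.00077), CA pyramidal (0.00077), small GTPase and cytoskeleton (0.0036) and ion channels (0.032). Fry was run without the variance trend used in the other tests. Each of these lists held hosts listed at 0 in all libraries of 1 group, where the spread is 0. Among them were Gabra2, Gabrb2, Adarb1, Dicer1, Srrm2, Cpne4, Arhgap35 and Cacna1d. Lists not called held such hosts too. Dnm1 was in the presynaptic list and Ptprk in the adhesion list (fry mixed adjusted p = 0.806 and 0.577). In settings run with fry after seeing the data, the small GTPase list was above 0.05 without Control replicates 1, 2 or 3 (0.382, 0.371 and 0.992) or CUS replicate 3 (0.0947). The ion channel list was above 0.05 without CUS replicates 1 or 2 (0.485 and 0.532). The CA pyramidal and small GTPase lists were not called without a filter or with the replicate block. The ion channel list was not called with the block or under quantile normalization. With 0.2 times the pseudocount the mixed test called 6 lists, adding adhesion and axon guidance. It called 1 list with 5 times the pseudocount (GABA and monoamine), 1 among hosts above the median mean (ion channels) and 0 among hosts above 0 in all 6 libraries. In the last 2 settings the GABA and CA lists had fewer than 5 hosts and were not tested.

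CircRNAs of host genes known from work on depression or stress were examined one by one, since the study asks about stress. No circRNA here was matched to a published one, because only the host symbol was shared. Of 10 listed hosts, 9 had 54 circRNAs, and 28 of these were tested. The most abundant were mmu_circRNA004516 of Tulp4, at 2034, 347 and 3433 in CUS against 1415, 1442 and 681 in Control, and mmu_circRNA005254 of Dym, at 1034 ± 464 against 1436 ± 435 (SD, n = 3 each). mmu_circRNA009989 of Sh3rf1 was at 1627, 202 and 666 in CUS against 311, 973 and 346, and mmu_circRNA010857 of Stag1, a cohesin subunit gene, at 318, 898 and 285 against 265.6, 73.1 and 77.1. mmu_circRNA010202 of Fto, an RNA demethylase gene, was at 345 ± 181 against 245 ± 130 (SD, n = 3 each). mmu_circRNA003008 of Homer1, a postsynaptic scaffold gene, was at 354, 538 and 514 in CUS and 164, 0 and 303 in Control. mmu_circRNA006064 of Tlk1 was at 522, 0 and 0 in CUS and 857, 78.2 and 1431 in Control. The leading circRNAs of Hipk2 and Mbnl1 were above 0 in 1 and 2 libraries and were not tested. With limma 0 of 28 passed over all circRNAs and 0 adjusted over the list alone (lowest adjusted p = 0.330). At an unadjusted p under 0.05 there were 2, mmu_circRNA004507 of Tulp4, listed at 0 in CUS, and mmu_circRNA006062 of Tlk1, listed at 0 in Control, both singled out after their values were seen. By host sum 6 of 8 tested hosts were higher and 2 lower, with Homer1 at 1085 ± 222 in CUS against 531 ± 308 in Control (SD, n = 3 each). That sum holds 2 Homer1 circRNAs, mmu_circRNA003008 and mmu_circRNA003011, that differed by at most 8 steps in any library and may share reads. Its log2 difference was 1.14, but 0.77 with the pair counted once, an alternative chosen after seeing the data, and 0.60 without Control replicate 2. Hipk2 was at 380, 88.8 and 0 in CUS against 109, 1127 and 407.

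The number of circRNAs above 0 was lower in every CUS library than in every Control library, at 4167 ± 154 against 4487 ± 143 (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest this design allows). Relative depth was also lower in CUS, at 86.8% ± 4.30 against 95.5% ± 4.62 of the deepest library (SD, n = 3 each; exact p = 0.1). With all libraries thinned to the lowest relative depth at an assumed 75 steps per read, an alternative chosen after seeing the data, the numbers were 4051 ± 58.6 and 4168 ± 44.1 (SD, n = 3 each), a difference of -118 in place of -320. It was -302 at 17 steps per read and -0.89 at 2 times 75. The size of 75 lies inside the range assumed for 1 read. The size of 17 is the lowest value of that range, and 2 times 75 lies above its highest. Under that assumption neither can be the average, so -302 and -0.89 are outer limits. The sources do not give the real read size. Counting only circRNAs at a level of at least 784, also chosen after seeing the data, gave 600, 592 and 574 in CUS and 594, 594 and 620 in Control, a difference of -14 (exact p = 0.4). Summed levels were 1.4% lower in CUS (exact p = 0.3). Total steps, the levels before division by the library factor, ran from 679141 in CUS replicate 1 to 840172 in Control replicate 1. That division evens out the sums, so this test cannot show whether stress changed total circRNA. If the factor was set from circRNA signal, thinning to relative depth would also remove a real drop in circRNA.

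**Figure D3:**
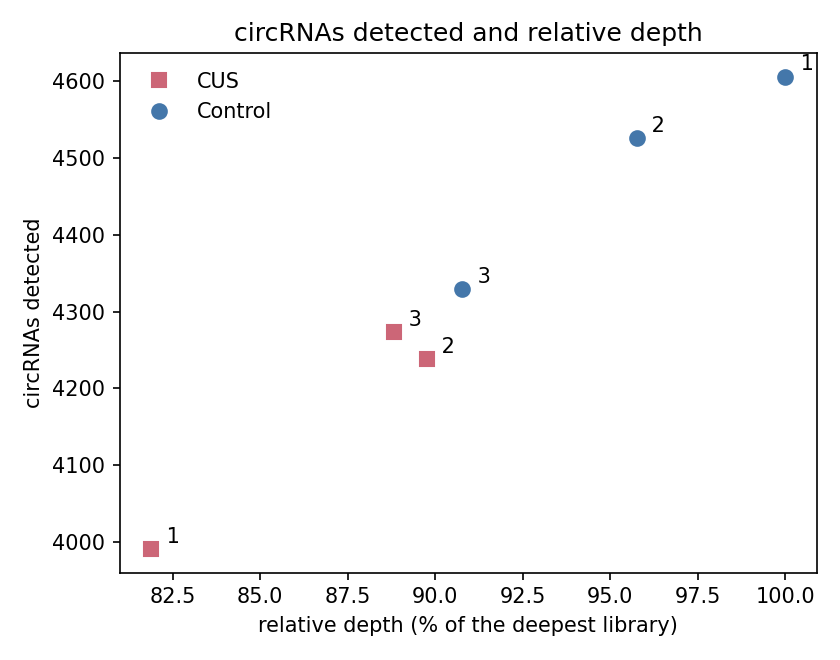
Number of circRNAs above 0 in each library (y axis, not starting at 0) against relative depth (x axis, percent of the deepest library), with Control as circles, CUS as squares and replicate numbers beside the points. CUS replicate 1 has the lowest relative depth, 81.9%, and holds the fewest circRNAs, 3991.

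Exonic circRNAs made up 92.7% ± 0.68 of the summed level in CUS and 92.1% ± 0.23 in Control (SD, n = 3 each; exact p = 0.3). Intergenic circRNAs made up 4.76% ± 0.30 and 5.26% ± 0.27 (SD, n = 3 each; exact p = 0.2). Intronic circRNAs made up 2.57% ± 0.39 and 2.61% ± 0.047 (SD, n = 3 each; exact p = 0.8), and this difference changed sign without CUS replicate 2 (0.13 percentage points). None of the 3 exact tests can go below p = 0.1.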

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

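The settings that required all 6 libraries, counted near-identical circRNAs once, rounded levels to multiples of 75 steps, thinned libraries by relative depth or total steps, compared detection at high levels, or ran fry outside its planned setting were chosen after seeing the data. The counts of 0 circRNAs, 0 hosts and 0 circRNAs of depression hosts past the adjusted threshold came out at 0 in every alternative run, and so did the count of lists in each setting run with camera or fry's directional test. Fry's mixed test called 5 lists, 6 with 0.2 times the pseudocount, 4 under quantile normalization, 3 without a filter and 2 with the replicate block. It called 1 with 5 times the pseudocount, 1 among hosts above the median mean, 0 among hosts above 0 in all 6 libraries and 4 to 5 without single libraries. The lists changed there. Known brain hosts were added without Control replicate 1, presynaptic genes without Control replicate 2, adhesion without Control replicate 3 and oligodendrocytes without CUS replicate 3. The count thus moved with the pseudocount added to levels of 0. At unadjusted p with a 2-fold change, 231 circRNAs became 91 among circRNAs above the median mean, where evenly spread p-values would give about 97. They became 32 among circRNAs above 0 in all 6 libraries, where evenly spread p-values would give about 40. Leaving out single libraries gave 186 to 212. The detection difference ran from -399 to -232 without single libraries. It was -14 (exact p = 0.4) at high levels and -89.9 when thinned by total steps at 75 steps per read. It reversed to 42.0 at 2 times 75. That size lies above the range assumed for 1 read, so the reversal is an outer limit only. Without single libraries the summed level ran from -40642 to -18523, and the class shares from 0.21 to 0.89 (exon), -0.25 to 0.13 (intron) and -0.65 to -0.34 percentage points (intergenic). The intron difference of -0.048 reversed to 0.094 as a share of detected circRNAs, and the cause was not tested. Of 110 named circRNAs and hosts, 8 log2 differences changed sign in some setting. Under quantile normalization the Zfp532 circRNA went to -0.19. Without single libraries the ranges were -0.23 to 0.29 (Zfp532), -0.64 to 0.23 (Gm47283), -0.32 to 1.06 (Sh3rf1) and -0.37 to 1.21 (Tulp4) for circRNAs, and -2.80 to 0.38 (Cacna2d1), -0.13 to 1.25 (Sh3rf1), -0.38 to 0.81 (Tlk1) and -0.20 to 1.50 (Dock10) for host sums, and the cause was not tested. Adjusted over the list alone, Gabra2, Gabrb2, Adarb1, Dicer1, Srrm2, Arhgap35 and Cpne4 passed without a trend, Ncor1 with the block, with 5 times the pseudocount and among hosts above the median mean, Tenm3 and Cpne4 with 0.2 times the pseudocount, and Tenm3 and Galntl6 without CUS replicate 2.

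No sign of pairing by the shared replicate numbers was seen: deviations of same-numbered libraries correlated at -0.011, -0.025 and -0.020 over circRNAs. With replicates this unlike each other, a weak pairing could go unseen. With the replicate block 0 circRNAs and 0 hosts passed, and camera and fry's directional test called 0 lists, while fry's mixed test called 2. There 215 circRNAs had an unadjusted limma p under 0.05 with a 2-fold change. The number of reads behind a value is unknown, and replicates of a group correlated at 0.27 to 0.32 over tested circRNAs, which limits what these counts can show.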

Other observations

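The tests in this part were all written down after the values they measure had been seen. Host genes widely known to give abundant brain circRNAs were mostly high in these libraries: 40 of 45 listed hosts had a circRNA, their median lay at percentile 86.9 of 3772 hosts, 7 were among the top 100 and 3 were below the median. Fat3 ranked 9, Slc8a1 22, Dlgap1 26 and Tulp4 41. Cdr1, whose locus gives one of the most abundant circRNAs described in mammalian brain, ranked 164, with a summed level of 2248 spread over 13 circRNAs, the highest of which, mmu_circRNA011118, was listed at 0 in Control replicate 2. Rims2 ranked 107, Homer1 638, Hipk3 1914 and Zfp609 2048.

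Microglial markers were nearly unmeasured, since 3 of 28 listed genes had a circRNA. Mertk, a phagocytic receptor gene, was at 208, 1714 and 979 in Control and 0, 0 and 275 in CUS, and Zfhx3 at 0, 348 and 660 in Control and 0, 188 and 0 in CUS. Among 538 hosts with at least 5 circRNAs, the leading circRNA held a median of 35.7% of the host's level. In 111 of them it held over 50%. Vascular and choroid markers summed to 772, 0 and 402 in CUS and 536, 812 and 402 in Control, and markers of neighbouring tissue to 1165 ± 338 and 1382 ± 336 (SD, n = 3 each).

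The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 0 circRNAs and 0 hosts past the adjusted threshold and 0 lists called by camera or fry's directional test. Each other split did the same, so all 10 gave as many, an outcome that a real count of 0 fixes in advance. At unadjusted p with a 2-fold change the real split gave 231 circRNAs and the highest other 236, and 2 of 10 splits gave at least as many. Fry's mixed test called 5 lists in the real split and at most 3 in the others, so 1 of 10 gave as many. CircRNAs above 0 in all libraries of one group and in none of the other numbered 167 (94 in Control and 73 in CUS) against at most 168 in another split, and 2 of 10 splits gave at least as many.

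Every CUS library held fewer circRNAs than every Control library. A lower depth of the CUS libraries cannot be told apart from other causes, because the library factor is not shown to follow sequencing depth. The share of the difference left after thinning also depends on how many steps 1 read is worth. With relative depth matched it was 94.4% at 17 steps and 36.8% at 75, and it was -13.1% at 2 times 75 with total steps matched. Under the range assumed for 1 read, neither 17 nor 2 times 75 can be the average, so 94.4% and -13.1% are outer limits. An effect of stress cannot be told apart from chance, because 3 against 3 cannot give an exact p under 0.1. The p was 0.1 after thinning by relative depth at 17 or 75 steps and 0.9 at 2 times 75. By total steps it was 0.2 at 75 and 0.4 at 2 times 75, where the difference was reversed.

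Among the 3930 circRNAs seen in a single library, 80.1% had an even number of steps and none had fewer than 34, which is 2 times the lowest value of 17. In circRNAs seen in several libraries 51.1% to 55.6% were even. If every such circRNA rested on 2 reads of equal weight, all totals would be even, but 19.9% were odd (standard error 0.64), which argues against that as the whole account. Independent reads with unrelated weights would give about 50%, and the share lay 30.1 percentage points above that with a standard error of 0.80, which argues against them as well. What causes the excess of even totals remains open. No biological explanation was tested.

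Libraries of one group correlated at 0.27 to 0.32 over tested circRNAs and 0.46 to 0.54 over those above 0 in all 6 libraries. Libraries of different groups correlated at 0.26 to 0.30 and 0.42 to 0.54, ranges that largely overlap these.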
